A study of Homo sapiens with 8 samples.

How the data were processed

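The data are poly(A) RNA sequencing of HCT116 cells, wild type (WT) or double knockout (DKO), starved without serum overnight or starved and then given EGF for 60 min. There are 8 libraries in 4 groups of 2. The labels write the targets as DNMT1a and DNMT3b, read here as DNMT1 and DNMT3B. The authors aligned reads to hg19 with STAR and used DESeq2, per the submitters' processing notes, which give no versions. The deposited table holds, for each of 21980 genes and each library, a signal that is the number of reads divided by 1 size factor per library. Every value is a whole multiple of the value of 1 read in its library within 1e-06, and the implied factors equal the median-of-ratios factors computed from the recovered whole reads. The counting step, the annotation and any filter of genes are not stated. Genes are named by symbol and no coordinates are given, since the annotation at hand (GENCODE v29 on GRCh38) is of another build; 19359 of the symbols matched its gene names and 19724 a RefSeq table. The library kit named in the labels does not keep the strand, so reads of a gene and of an overlapping antisense gene cannot be separated.

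The tests were fixed before the data were examined, for raw counts first and for normalised values otherwise; the second form was used because the deposited values are normalised. Genes with a value of at least 10 in at least 2 libraries (16972) were kept. Values were taken as log2(value + 1) and fitted with limma-trend (limma 3.58.1, R 4.3.3) in 1 model of 4 groups, with 4 residual and 6.90 prior degrees of freedom. The 5 contrasts were EGF against starved in WT and in DKO, the difference of those responses, and DKO against WT without and with EGF. A Benjamini-Hochberg adjusted p under 0.05 in a two-sided test was called. The overlap of both EGF responses was counted beside the overlap of independent lists.

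Of 20 gene lists fixed before the data were examined, 19 were tested with camera at a preset correlation of 0.01, and again with an estimated one; 410 of their 423 members were found. None of the mitochondrial list was in the table, so that list was not analysed. The tested lists were immediate early transcription factors, feedback regulators of ERK signalling and early mRNA, ligands and secreted factors, EGF receptor family and RAS-ERK components, SRF and actin targets, NF-kB targets, growth arrest and FOXO genes, glucocorticoid receptor targets, cancer-testis and germline genes, genes hypermethylated in colorectal cancer, interferon-stimulated genes, HLA class I presentation, imprinted genes, DNA methylation machinery, p53 targets, cell cycle genes, cholesterol synthesis, intestinal and WNT target genes, and markers of fibroblasts, endothelium and blood cells.

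The genes named in the text follow a rule fixed at the same time. For each contrast they are the 10 largest rises and falls among called genes with a mean of at least 10 in the higher group, with all libraries of the higher group above those of the lower. From each list they are up to 4 members, called ones with the smallest adjusted p first, then by expression. DNMT1, DNMT3A, DNMT3B and EGFR belong to every contrast, and the text names fewer than the rule allows. Genes named outside it are marked as chosen after their values were seen. Some genes that the rule names are not reported here. Where a group had few reads, the ratio of reads is given with a 95% counting interval, and where it had none the fold is against a floor of 3 reads over the group.

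Alternatives fixed in advance were quantile normalisation, no filter, a stricter filter (a value of 50), pseudocounts of 0.1 and 5, a fit of the compared groups only, the replicate number as a block, leaving out each library in turn, other thresholds for the overlap and the estimated correlation. Chosen after seeing the data were edgeR (4.0.16) with TMM or RLE factors, DESeq2 (1.42.0) and limma-voom on the recovered reads, limma on reads scaled by TMM or by library totals, a filter on the compared groups, and removal of the trend with GC content and length. DESeq2 had been fixed in advance for the overlap alone. EdgeR with TMM factors was the test fixed in advance for raw counts, and its use on recovered reads was decided afterwards. GC content was known for 93.3% of the tested genes. The fit was tested on simulated data with added changes of 1.5-, 2- and 4-fold. It recovered 59.7%, 92.5% and 98.5% of the changed genes for EGF in DKO and 25.4%, 70.1% and 92.4% for the difference. For DKO against WT starved it recovered 74.6%, 94.0% and 100%. False calls in these comparisons numbered 0, 7 and 4. The simulation gave a gene the same spread in all libraries and changed only genes with a mean of at least 10 in both genotypes. In the data the DKO libraries with EGF lay farther apart than other pairs (chi-square per degree of freedom 10.7 against 1.47 to 2.45).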

Results

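Poly(A) RNA was sequenced from HCT116 cells, a human colorectal cancer line, in 8 libraries that fell into 4 groups of 2. Wild-type (WT) cells and double-knockout (DKO) cells, made to lack the DNA methyltransferases DNMT1 and DNMT3B, were each collected after starvation without serum overnight or after 60 min of epidermal growth factor (EGF) added to starved cells. The comparisons ask how cells respond to EGF, how the genotypes differ with and without it, and whether the response itself differs between genotypes. The reads assigned to genes came to about 17376700 and 21240400 in the starved WT libraries and 19193900 and 15893900 in WT with EGF. In DKO they came to about 18246200 and 18926800 starved and 16877200 and 19575600 with EGF. Between 14218 and 14384 genes reached 10 normalised reads in a WT library, and between 16467 and 16701 did so in a DKO library. The first principal component held 94.5% of the variance and separated the genotypes. Levels are normalised reads as mean ± SD (n = 2 libraries), and changes are log2 fold changes on the log2(value + 1) scale from limma, with Benjamini-Hochberg adjusted p-values. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The DKO libraries with EGF lay farthest apart, with a chi-square per degree of freedom of 10.7 against 1.47 to 2.45 in the other groups.

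The targeted genes were lower in DKO. DNMT1, the maintenance methyltransferase, stood at 8748 ± 514 in starved WT and 8403 ± 105 in WT with EGF, and at 1035 ± 74.7 in starved DKO and 931 ± 113 in DKO with EGF. DNMT3B, a de novo methyltransferase, stood at 586 ± 5.15 and 567 ± 63.8 in WT and at 212 ± 8.87 and 212 ± 12.9 in DKO. The change in starved cells was −3.08 for DNMT1 (SE 0.0856, limma adjusted p = 4.79e-10) and −1.46 for DNMT3B (SE 0.104, limma adjusted p = 3.52e-07), and each DKO library lay below each WT library. DNMT3A, the de novo enzyme left intact by design, rose from 271 ± 39.4 to 519.7 ± 5.14 (0.94, limma adjusted p = 1.71e-05). RNA of both targets was still present in DKO, and the values do not show whether it encoded an active protein.

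In WT cells EGF raised a small set of early growth factor genes. EGR1, a zinc finger transcription factor induced within minutes of growth factor signalling, rose from 4539.5 ± 453 to 11723 ± 285 (1.37, SE 0.0758, limma adjusted p = 3.02e-05). Its relatives EGR2 and EGR3 each rose by 1.32, and the AP-1 genes FOSB, ATF3 and JUN rose by 0.95, 0.65 and 0.59. KLF2 (0.83), CYR61, which encodes a secreted matrix protein (0.72), the small GTPase gene RHOB (0.59) and KLF10 (0.51) also rose. DUSP6 and DUSP5, phosphatases that switch off ERK, rose by 0.42 and 0.45, and MCL1, an anti-apoptotic gene named after its values were seen, rose by 0.43. FOS, outside the rule for named genes in WT, stood at 418 ± 48.9 before and 585 ± 14.3 after EGF, a difference that did not pass (limma adjusted p = 0.142). DNMT1, DNMT3A, DNMT3B and EGFR did not pass either, with changes between −0.06 and 0.03.

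Of the 16972 genes tested in WT, 13 rose and 4 fell with EGF, and 1529 had an unadjusted p under 0.05. The 4 falls were SPATA31A1, SPATA31A3, CLEC2L and GPX7, all outside the rule for named genes in WT and named after their values were seen. They had 10 reads (SPATA31A1) or 5 reads (each of the others) in starved WT and 0 reads with EGF. Of 24 immediate early transcription factors 8 rose (17 adjusted over the list alone), and the list lay above other genes (camera adjusted p = 2.59e-30; adjusted p = 0.0605 with an estimated correlation). Of 24 feedback regulators 2 rose, 10 adjusted over the list alone (camera adjusted p = 1.22e-11; adjusted p = 0.181 with an estimated correlation). Of 19 ligands and secreted factors 1 rose, 5 adjusted over the list alone (camera adjusted p = 4.47e-06; adjusted p = 0.0605 with an estimated correlation). Glucocorticoid receptor targets (adjusted p = 0.0200) and cancer-testis genes (0.0366) also passed upward, and interferon-stimulated genes (0.0123) and HLA class I genes (0.0366) downward. No member of those 4 lists passed alone over all genes, and with an estimated correlation their adjusted p-values were 0.181, 0.181, 0.370 and 0.599. Adjusted over the list alone 1, 2, 1 and 0 of their members rose and none fell. The other 12 lists did not pass. A fit of the WT libraries alone called 0 genes with limma (1334 higher and 1363 lower at an unadjusted p under 0.05), while edgeR called 29 and DESeq2 28 with all libraries. The count moved to 5 without either starved DKO library and to 67 (28 higher and 39 lower) without either DKO library with EGF. It was 31 (22 and 9) without starved WT replicate 2, and 62 (17 and 45) and 32 (16 and 16) without EGF-treated WT replicates 1 and 2. Quantile scaling called 14 rises and 1 fall.

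In DKO cells the same treatment gave larger and more numerous rises, though with a pseudocount of 0.1 the numbers were close, 59 in DKO and 56 in WT. EGR1 went from 997 ± 30.7 to 19215 ± 1391 (4.27, SE 0.0758, limma adjusted p = 1.50e-10). EGR3 went from 43.5 ± 2.27 to 682 ± 45.8 (3.94), EGR2 from 33.9 ± 3.35 to 352 ± 16.5 (3.34) and FOS from 430.4 ± 7.68 to 2499.7 ± 244 (2.53). FOSB rose by 2.25, JUN by 1.62 and the nuclear receptor gene NR4A1 by 1.59. CYR61 and CTGF, which encode related secreted matrix proteins, rose by 1.62 and 1.52, and CTGF reached 1557 ± 10.4. Feedback genes followed, with DUSP2 at 1.68, the mRNA decay factor ZFP36L1 at 0.79, DUSP6 at 0.72 and SPRY4 at 0.69 (limma adjusted p = 1.06e-04 or below for each). MYC, named after its values were seen, rose by 0.47 from 2326 ± 99.0 to 3216 ± 191, which stayed below the starved WT level of 9655 ± 184.

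**Figure D1:**
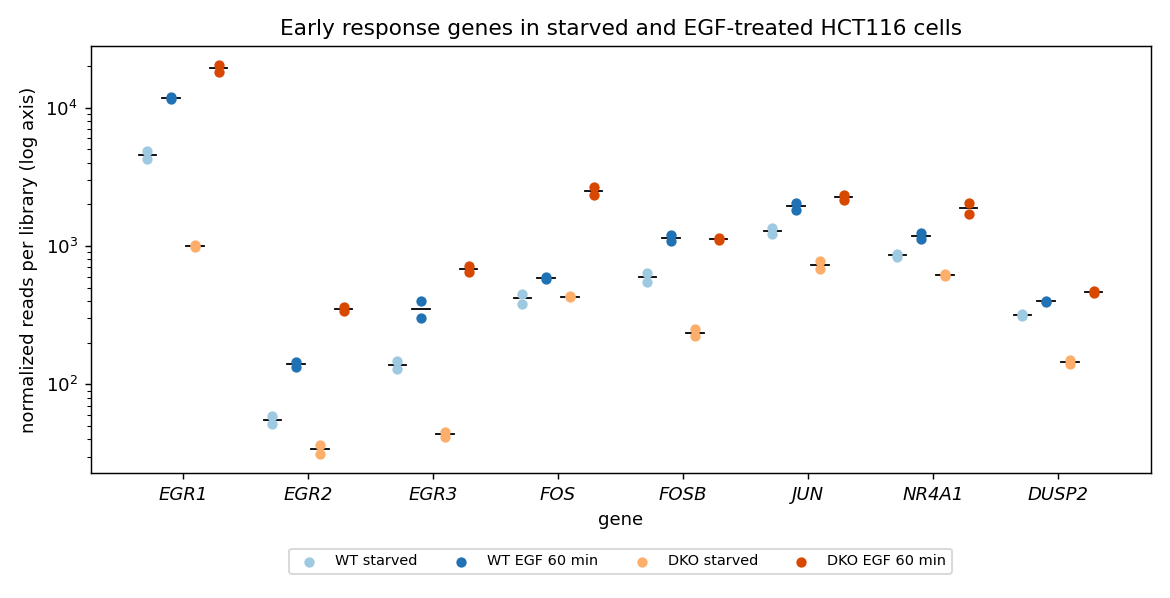
Normalised reads per library (log axis) of 8 early response genes in starved and EGF-treated WT and DKO HCT116 cells; each point is 1 library and each line the mean of 2. EGR1 starts lower in DKO (997 against 4539.5) and ends higher (19215 against 11723).

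Of the 16972 genes tested in DKO, 82 rose and 9 fell with EGF, 22 and 3 of them by 2-fold or more, and 1357 had an unadjusted p under 0.05. Of 24 immediate early factors 20 rose, 22 adjusted over the list alone (camera adjusted p = 5.68e-79; adjusted p = 0.00993 with an estimated correlation). Of 24 feedback regulators 13 rose, 18 adjusted over the list alone (adjusted p = 3.43e-36; adjusted p = 0.0276 with an estimated correlation). Of 19 ligands and secreted factors 5 rose, among them the chemokine gene CXCL8 (1.19) and the cytokine gene LIF (0.62), while 9 rose and 1 fell adjusted over the list alone (adjusted p = 1.65e-13; adjusted p = 0.0123 with an estimated correlation). DUSP1 (0.99) and ERRFI1 (0.55), which brake MAP kinase and EGF receptor signalling, were the 2 risers among glucocorticoid receptor targets. AEN (0.55) and BTG2 (0.81) rose among p53 targets, and THBS1 (0.47) among genes hypermethylated in colorectal cancer. Those glucocorticoid, p53 and cholesterol lists passed (adjusted p = 0.00561, 0.0385 and 0.0438), as did SRF targets (8.35e-04), NF-kB targets (0.0110) and cell cycle genes (0.0438). With an estimated correlation their adjusted p-values were 0.130, 0.211, 0.211, 0.141, 0.406 and 0.374, so that none of these 6 held. The cholesterol list had a median of −0.00 and a mean of 0.09, opposite in sign. The other 10 lists did not pass.

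The falls in DKO were fewer, with a median of −0.73. AXIN2, a target of WNT signalling, went from 1189 ± 7.76 to 777 ± 19.6 (−0.61, SE 0.116, limma adjusted p = 0.0482), and PNRC1, a nuclear receptor coactivator gene, from 465 ± 34.4 to 282 ± 42.4 (−0.73). The neuropeptide gene NPW changed by −1.03, TPGS1 by −1.30, CTXN1 by −0.59 and the nuclear RNA NEAT1 by −0.36. NME2 (−1.16) and DDTL (−0.61) are uncertain, since each has a near-identical neighbour that can share its reads; the small nucleolar RNA gene SNORD104 (−0.95), outside the rule for named genes, completed the 9. Removing the trend with GC content and length left 8 of the 9 falls called, and CTXN1 stood at −0.29 (limma adjusted p = 0.235). Calls depended on single libraries. Without EGF-treated DKO replicate 2 many more genes were called, with rises and falls in similar numbers. Without either starved DKO library fewer genes were called, and no fall was among them. Quantile scaling called 100 rises and 43 falls.

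The EGF response differed between genotypes for 17 genes, each with a larger log2 change in DKO. The difference was 2.89 for EGR1 (SE 0.107, limma adjusted p = 4.25e-07), 2.62 for EGR3, 2.05 for FOS, 2.02 for EGR2, 1.36 for DUSP2 and 1.30 for FOSB. NR4A1 (1.12), JUN (1.03), JUNB (0.93), CYR61 (0.89), KLF10 (0.89), IER2 (0.78), FOSL1 (0.71), IER3 (0.66), MIDN (0.55) and RHOB (0.50) followed, of which IER2, FOSL1, MIDN and RHOB were named after their values were seen. SPATA31A1 had the largest difference, 3.10, which combined 10 reads falling to 0 in WT with a DKO change of 0.52 that did not pass. Of the 17 genes 10 were lower and 1 was higher in starved DKO, and 14 were higher and 1, FOSL1, was lower in DKO with EGF. EGR1, EGR3, EGR2 and NR4A1 were among the 7 that were both lower when starved and higher with EGF. FOS stood at 418 ± 48.9 in starved WT and 430.4 ± 7.68 in starved DKO and was higher in DKO only with EGF, by 2.09 (limma adjusted p = 1.33e-08). FOSB reached 1143 ± 75.0 in WT and 1126 ± 33.7 in DKO, so that its larger change came with a lower starved level (−1.32).

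**Figure D2:**
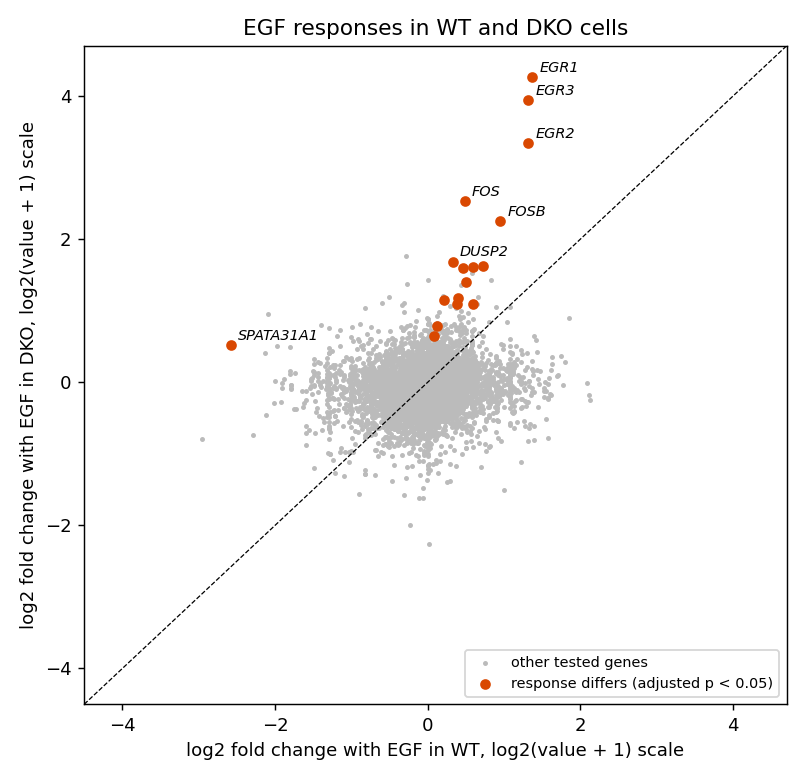
Log2 fold change with EGF in DKO against that in WT for each tested gene; orange points are the 17 genes whose response differed (limma adjusted p under 0.05) and the dashed line marks equal changes. EGR1, EGR3, EGR2 and FOS lie far above the line.

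Of 24 immediate early factors 11 responded more in DKO, 18 adjusted over the list alone (camera adjusted p = 1.28e-59; adjusted p = 0.0172 with an estimated correlation). Feedback regulators (2, or 10 adjusted over the list alone; adjusted p = 2.93e-20), ligands and secreted factors (1, or 3; adjusted p = 9.36e-05), SRF targets (0, or 0; 9.36e-05) and interferon-stimulated genes (0, or 0; 0.00183) also passed upward. With an estimated correlation their adjusted p-values were 0.0792, 0.0792, 0.118 and 0.309. The other 14 lists did not pass. No gene had a smaller response in DKO with limma, and 271 did at an unadjusted p under 0.05; edgeR, DESeq2 and voom also called 0, while limma called 10 (beside 31 larger responses) with a pseudocount of 0.1, 4 without starved WT replicate 2 and 1 and 2 without EGF-treated WT replicates 1 and 2. The starved and EGF comparisons share libraries with the difference: unchanged groups simulated 100 times gave a mean of 12.04 genes lower when starved and 11.91 higher with EGF among the top 17. Calls fell to 7 and 3 without starved DKO replicates 1 and 2, while the smallest share of a difference kept in any fit that left out 1 library was 0.881, for NR4A1.

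The 13 genes that rose in WT all rose in DKO too, where independent lists of these sizes would share 0.0628 genes, and none of the falls was shared (0.00212 by chance). The WT and DKO changes share no library, but the spread of each gene came from all libraries in both tests. The lists are thus not independent, and a gene of small spread passes more easily in both. The median change of the 13 genes, EGR1, FOSB and JUN among them, was 0.65 in WT and 1.42 in DKO. The 82 DKO risers had a median of 0.69 in DKO and 0.29 in WT, where 78 changed in the same direction; they were chosen for their DKO values. Across all genes, which are not independent replicates, the changes had a Pearson correlation of 0.19 and a Spearman correlation of 0.32. Both changes also fell with GC content (Pearson correlation −0.28 in WT and −0.32 in DKO over 15842 genes), and with the trend of GC content and length removed, a setting chosen after seeing the data, the correlations between WT and DKO went from 0.192 to 0.113 (Pearson) and from 0.331 to 0.167 (Spearman) on these genes. The number of genes called in the same direction in both genotypes moved to 0 with only the compared groups in the fit, and to 4 without either starved DKO library. It was 7 without either starved WT library or EGF-treated WT replicate 2, and 26 without EGF-treated DKO replicate 1. Without EGF-treated DKO replicate 2 it was 62, made up of 28 shared rises and 34 shared falls.

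Without EGF, DKO cells expressed many genes that were silent or nearly silent in WT. UCHL1, a neuronal deubiquitinase gene, went from 3.60 ± 1.22 to 6210.1 ± 38.7, a ratio of 1768 (95% counting interval 858 to 4399). MAEL, which protects germ cells from transposons, had 0 reads in starved WT and 1057 ± 56.7 in starved DKO, at least 703-fold higher against a floor of 3 reads over the group. ZNF266 was at least 571-fold higher on the same terms. TSPYL5 was higher by a ratio of 1399 (387 to 11560), NPTX2 by 1218 (337 to 10066), FBLN2 by 1204 (333 to 9946), BASP1 by 1882 (337 to 74354), DPEP3 by 779 (334 to 2401) and the imprinted RNA MEG3 by 1776 (318 to 70169). TUBA3C (929, 450 to 2311) has near-identical tubulin genes and is uncertain. Intervals and floors cover counting error only. In all, 236 genes had a mean of at least 100 in starved DKO and at most 3 reads in starved WT, and 0 genes showed the reverse.

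**Figure D3:**
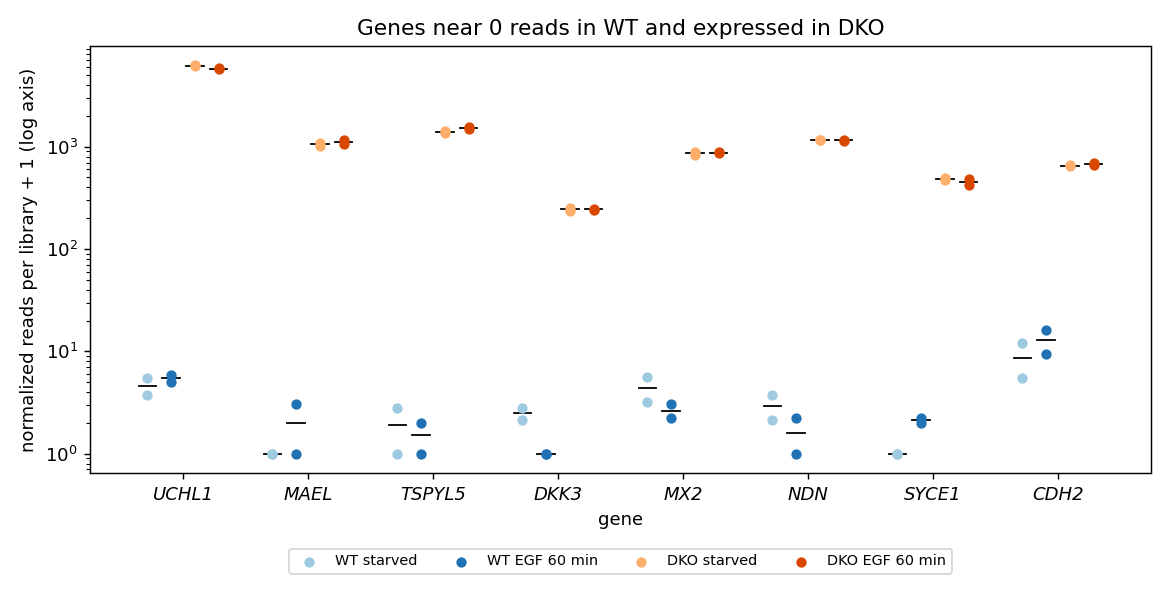
Normalised reads + 1 per library (log axis) of 8 genes near 0 reads in WT; each point is 1 library and each line the mean of 2. UCHL1 lies at 6210.1 in starved DKO and 3.60 in starved WT, and the DKO libraries with and without EGF lie close together.

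Fewer genes were strongly lower in starved DKO. NR5A2, a nuclear receptor gene, fell from 1806 ± 19.3 to 24.3 ± 1.19 (−6.16), and EREG, which encodes the EGF receptor ligand epiregulin, from 2259.8 ± 6.33 to 32.9 ± 7.04 (−6.07, limma adjusted p = 3.26e-10). WNT16, a secreted WNT ligand gene, fell from 1582 ± 9.80 to 39.4 ± 0.881, IL20RA from 420.4 ± 7.48 to 7.79 ± 0.474 and ALPK2 from 311 ± 34.4 to 7.32 ± 1.13. SFTA1P changed by −4.60. CIB4 had 0 reads in starved DKO and was at least 21.5-fold lower. The ratios of WT to DKO were 61.3 (16.6 to 512) for CSF2RA, 96.3 (16.8 to 3848) for FGF13 and 73.4 (12.7 to 2940) for MAGEE1, which had 1 or 2 reads in DKO.

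The lists tied to DNA methylation moved upward in starved DKO. The filter keeps a gene silent in WT mostly when it is higher in DKO, so that rises of such genes are partly set by it. It kept 31 of 33 cancer-testis, 31 of 38 hypermethylated and 20 of 22 imprinted genes found. Of 31 cancer-testis and germline genes 27 rose and 3 fell (camera adjusted p = 1.45e-09; adjusted p = 0.0355 with an estimated correlation). SYCE1, a component of the meiotic synaptonemal complex, was at least 318-fold higher, and PRAME rose by 2.10. GAGE1 (5.24) and PAGE1 (3.68) belong to families of near-identical copies and are uncertain. Of 31 genes hypermethylated in colorectal cancer 25 rose and 4 fell, with SPARC up by 2.84, VIM by 1.44 and DKK3, a WNT antagonist gene, by a ratio of 163 (55.3 to 791) (adjusted p = 2.14e-05; adjusted p = 0.0579 with an estimated correlation). Of 20 imprinted genes 16 rose and 4 fell (adjusted p = 0.00321; adjusted p = 0.0819 with an estimated correlation). PEG10 rose by 4.45, KCNQ1OT1 by 2.27 and NDN by a ratio of 577 (225 to 2118). Of 17 genes of the DNA methylation machinery 4 rose and 8 fell, with TET3 at −0.84, and the list did not pass (adjusted p = 0.159).

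Interferon-stimulated genes were higher almost as a whole, 30 of 31 with no fall (adjusted p = 1.62e-10; adjusted p = 0.0642 with an estimated correlation). The antiviral genes MX2 (ratio 245, 119 to 610), MX1 (4.75) and IFIT1 (3.34) and the transcription factor gene IRF9 (2.38) were examples. Of 12 HLA class I presentation genes 9 rose and 1 fell, including PSMB8, an immunoproteasome subunit (3.67), HLA-B (1.37) and HLA-C (1.02) (adjusted p = 0.0151; adjusted p = 0.512 with an estimated correlation). HLA genes share reads among themselves. Of 20 growth arrest and FOXO genes 15 rose and 1 fell (adjusted p = 0.00251; adjusted p = 0.202 with an estimated correlation). TXNIP, a glucose-responsive thioredoxin inhibitor, rose by a ratio of 90.8 (52.9 to 171), ID2 by 2.70, ID1 by 2.15 and FOXO1 by 1.01. Markers of fibroblasts, endothelium and blood cells, 7 of which already stood at 10 or more in starved WT, rose in 15 of 16 cases with no fall (adjusted p = 2.71e-04; adjusted p = 0.0642 with an estimated correlation). CDH2, N-cadherin, went from 7.70 ± 4.58 to 651 ± 8.12, and COL1A2 rose by a ratio of 116 (31.9 to 967). PDGFRA was at least 24.1-fold and PTPRC, a leukocyte gene, at least 7.61-fold higher, though at means of 36.3 and 11.5. The filter left out DCN, LUM, POSTN and CDH5, which were under 10 in starved WT and starved DKO.

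**Figure D4:**
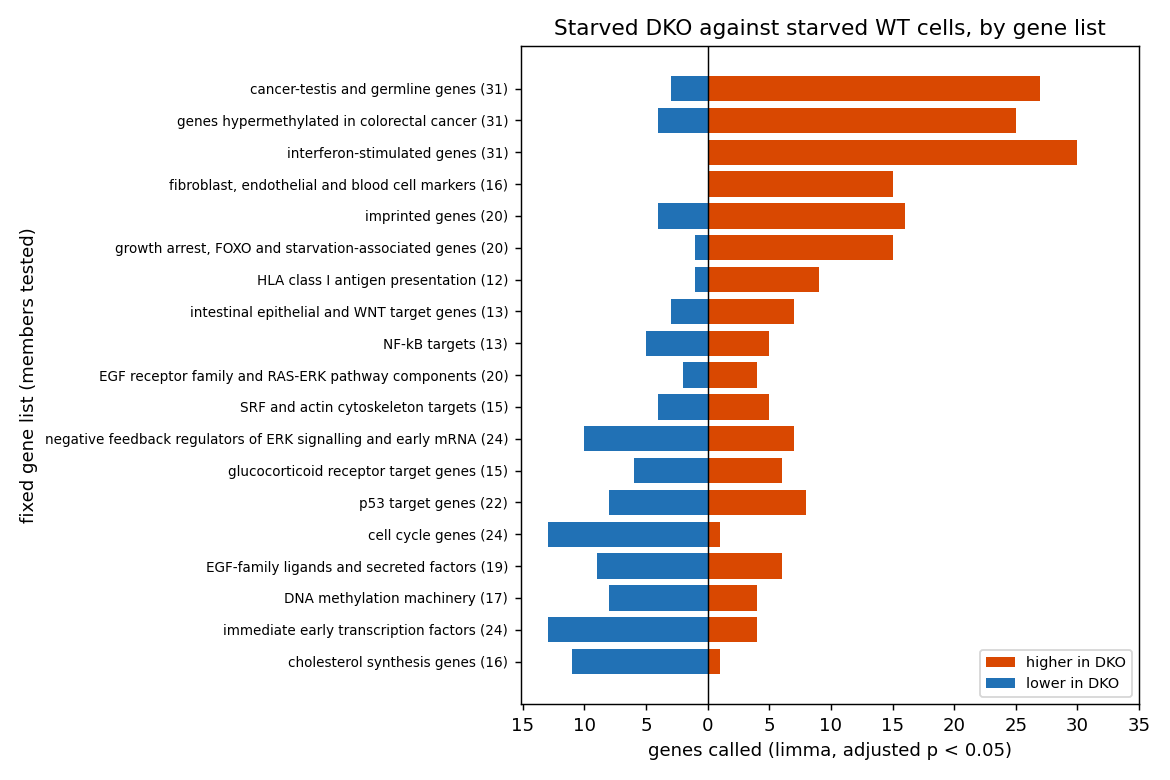
Genes of each fixed list higher (right) or lower (left) in starved DKO than in starved WT, as counts of genes with a limma adjusted p under 0.05; the number tested is in brackets. Interferon-stimulated genes show 30 rises and 0 falls, and cholesterol synthesis genes 1 rise and 11 falls.

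Several signalling and growth genes were lower in starved DKO. AREG, another EGF receptor ligand, fell from 1605 ± 1.07 to 122 ± 10.5 (−3.71, SE 0.106, limma adjusted p = 5.26e-10), PLAU by 2.37 and VEGFA by 1.72 on the log2 scale. Named after their values were seen, TGFA went from 491 ± 1.03 to 244 ± 6.85 and BTC, a ligand at trace levels in DKO, changed by −2.21, while HBEGF rose by 0.89; EPGN, at 8.67 ± 1.95 and 7.76 ± 3.07, did not pass. Of these 6 EGF-family ligands 4 were lower. Of the 19 ligands and secreted factors 6 rose and 9 fell (adjusted p = 0.140); the list passed under quantile scaling (adjusted p = 0.0249) and library-total scaling (adjusted p = 0.0177). EGFR itself rose from 617 ± 97.9 to 886 ± 19.8 (0.53, limma adjusted p = 0.00104). Of 24 immediate early factors 4 rose and 13 fell, with MYC at −2.05, EGR1 at −2.18, FOSB at −1.32 and FOSL1 at −1.05 (adjusted p = 0.00226; adjusted p = 0.282 with an estimated correlation). Of 24 feedback regulators 7 rose and 10 fell (adjusted p = 0.449); TRIB1 (−2.01) and ERRFI1 (−1.31) fell, and DUSP6 (1.77) and LRIG1 (3.81), an EGF receptor antagonist, rose. Of 20 receptor and RAS-ERK components 4 rose and 2 fell, with PTPN11 at −0.83, ERBB3 at −0.95, MAPK3 at 0.51 and SHC1 at 0.30 (adjusted p = 0.808).

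**Figure D5:**
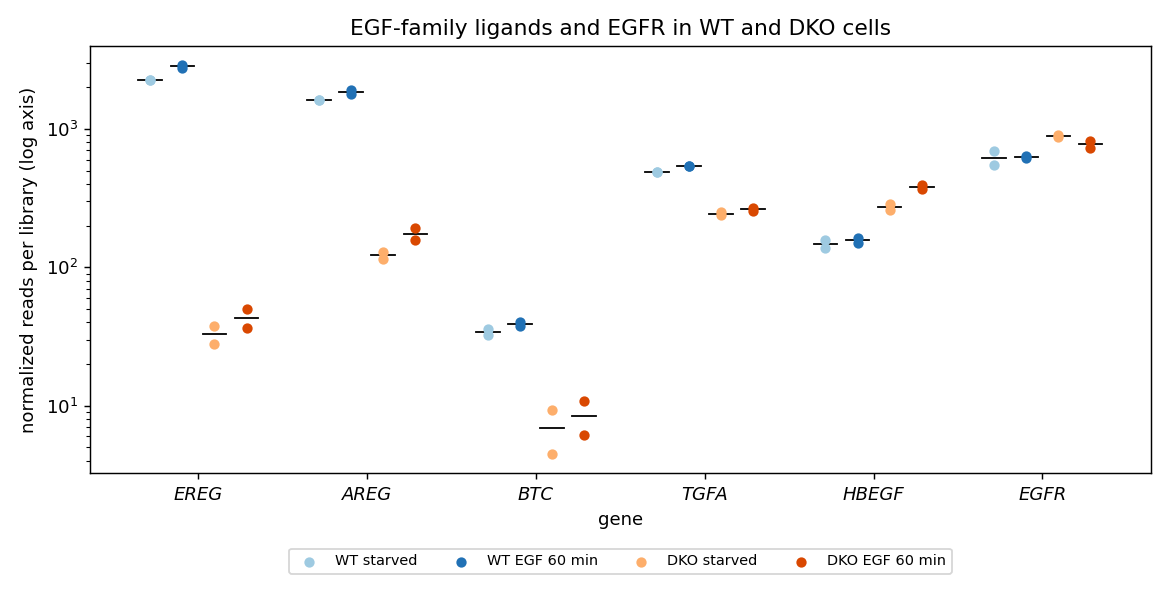
Normalised reads per library (log axis) of 5 EGF-family ligand genes and EGFR; each point is 1 library and each line the mean of 2. EREG lies at 2259.8 in starved WT and 32.9 in starved DKO, while HBEGF and EGFR are higher in DKO.

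Cholesterol synthesis genes fell in 11 of 16 cases, with FDPS, which makes the isoprenoid precursor of sterols, at −0.92, whereas SQLE rose by 5.08 from 22.3 ± 3.18 to 782 ± 28.5. The list passed (adjusted p = 6.41e-04; adjusted p = 0.0650 with an estimated correlation) but not under quantile scaling (adjusted p = 0.215). Of 24 cell cycle genes 1, CCND1 (0.80), rose and 13 fell, among them the replication helicase genes MCM7 (−0.81), MCM3 (−0.60) and MCM6 (−0.59) (adjusted p = 0.00188; adjusted p = 0.168 with an estimated correlation); under quantile scaling the list did not pass (adjusted p = 0.843), with a median of −0.0523 and a test pointing up. The remaining lists did not pass. SRF targets had 5 rises and 4 falls (ANKRD1 3.44, TPM1 0.82; adjusted p = 0.961), and NF-kB targets 5 and 5 (TNFAIP3 −2.66, ICAM1 1.17; adjusted p = 0.808). Glucocorticoid receptor targets had 6 and 6 (FKBP5 −1.51, CDKN1C 1.91; adjusted p = 0.721), and p53 targets 8 and 8 (EDA2R −2.75, TP53INP1 1.49; adjusted p = 0.528). Intestinal and WNT target genes had 7 rises and 3 falls (adjusted p = 0.528), with TFF3 higher by a ratio of 163 (44.9 to 1355), AXIN2 at 2.20 and EPCAM, an epithelial adhesion gene, at −1.25, and CDX1 at least 25.6-fold higher. Adjusted over the list alone the counts in starved cells were the same except for feedback regulators (8 and 10) and glucocorticoid receptor targets (7 and 7).

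Over all genes, 6290 were higher and 4966 lower in starved DKO with limma, 3910 and 600 of them by 2-fold or more. The split depended on the scaling: it was 4602 and 6628 after quantile scaling, 7952 and 3116 after scaling by library totals and 6251 and 5028 with TMM. The median change of all tested genes was 0.06 as deposited, −0.11 after quantile scaling, 0.24 after library-total scaling and 0.05 with TMM, and changes are to be read relative to it.

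With EGF the genotypes differed much as they did without it. UCHL1 stood at 5789.7 ± 55.5 in DKO and 4.46 ± 0.582 in WT, and TSPYL5 and NDN were higher by ratios of 2731 (490 to 107908) and 2087 (374 to 82483). EREG (−6.01), NR5A2 (−5.88) and WNT16 (−5.61) were lower, TBX3 went from 212 ± 28.5 in WT to 7.35 ± 4.06 in DKO, and CSF2RA was at least 47.8-fold lower. Among early genes FOS (2.09), JUNB (1.09) and KLF10 (0.96) were now higher in DKO while MYC stayed lower (−1.68), and 13 of the 24 were higher and 5 lower (adjusted p = 0.199). DUSP6 (2.07), LRIG1 (4.01) and SPRY2 (1.77) were higher and TRIB1 (−1.81) lower among feedback regulators, 13 and 4 of 24 (adjusted p = 0.317). EGFR differed by 0.30 (limma adjusted p = 0.0260).

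Limma called 6304 genes higher and 5011 lower in DKO with EGF, 3849 and 627 of them by 2-fold or more; the split was 4646 and 6628 after quantile scaling, 7675 and 3377 after library-total scaling and 6214 and 5154 with TMM. Of the called genes 5768 were higher and 4459 lower both with and without EGF, and 8 changed sides. Independent lists would share 2336 and 1466, but both sets of calls used the same spread for each gene. Interferon-stimulated genes (31 of 31 higher; adjusted p = 6.00e-11), markers of other cell types (16 of 16 higher; 1.06e-04), cancer-testis genes (27 higher, 3 lower; 5.41e-09), hypermethylated genes (23 and 3; 2.18e-05) and imprinted genes (14 and 3; 0.00513) passed upward. Growth arrest genes (14 and 2; 0.00763) and HLA genes (9 and 0; 0.00699) did so too, and cell cycle (2 and 14; 0.00513) and cholesterol genes (2 and 11; 0.00513) passed downward. With an estimated correlation the adjusted p-value was 0.0401 for cancer-testis genes and between 0.0581 and 0.504 for the other 8. The remaining lists, among them SRF targets (7 and 1 of 15) and ligands (7 and 8 of 19), did not pass. Adjusted over the list alone the counts differed for immediate early factors (14 and 5), receptor and RAS-ERK components (3 and 2), NF-kB targets (7 and 5) and cholesterol genes (3 and 11). Under quantile scaling cell cycle genes (adjusted p = 0.923, median −0.00544) and cholesterol genes (0.345) did not pass, and immediate early (0.00775), feedback (0.0102) and SRF lists (0.0134) passed upward.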

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

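The test of the difference between the EGF responses was planned; of the tests weighed here, that of counting noise was written before its result was seen, and all others were chosen after. The response to EGF differed between DKO and WT for 17 genes, each found by the limma test of the difference itself. On the log2 scale DKO minus WT was 3.10 for SPATA31A1, 2.89 for EGR1, 2.62 for EGR3, 2.05 for FOS, 2.02 for EGR2, 1.36 for DUSP2, 1.30 for FOSB, 1.12 for NR4A1, 1.03 for JUN and 0.93 for JUNB. It was 0.89 for CYR61, 0.89 for KLF10, 0.78 for IER2, 0.71 for FOSL1, 0.66 for IER3, 0.55 for MIDN and 0.50 for RHOB. With groups of 2 libraries no single library can be tested as lying apart from its group.

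The larger responses of EGR1, EGR3, FOS and the others in DKO could come from the authors' size factors. Quantile, library-total and TMM scaling kept 17, 15 and 16 of the 17 calls, so that at least 15 held under each, which argues against the scaling as the whole cause. They could also follow from the lower starved level of genes such as EGR1 in DKO alone. Of the 17 genes 14 were higher in DKO with EGF, but this comparison shares libraries with the test that chose them. Unchanged groups simulated 100 times gave a mean of 11.91 and at most 15 among the top 17, so the 14 cannot decide. Of the 14 genes higher with EGF, 7 were not lower in DKO when starved, FOS among them, and 1, SPATA31A1, was already higher. FOS differed by 0.05 when starved and by 2.09 with EGF, so that its larger response did not come with a lower starved level. Simulated genes that differed only when starved gave a mean of 0.17 and at most 2. That simulation does not give the number to expect, since it set both genotypes equal with EGF. In the data 6304 of all 16972 tested genes were higher in DKO with EGF. Loss of the methyltransferases may be behind the larger responses, yet the labels name 1 knockout source, so that the lost enzymes and any other difference of that DKO line cannot be told apart. A larger response of early genes in cells made to lack DNMT1 and DNMT3B remains a hypothesis, which several independently made knockout lines could test.

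The 4 falls in WT, SPATA31A1, SPATA31A3, CLEC2L and GPX7, were at trace levels. Counting noise may account for them: of 931 genes with 5 to 20 reads over the WT libraries, 9 had at least 5 reads in 1 WT condition and none in the other, where random division of the reads gave 11.7 (95% range 6 to 19). All 9 were starved only, against 7.46 expected, and 0 were EGF only, against 4.28. Spread borrowed from the DKO libraries, where these genes are higher, is a further explanation, which can hold together with counting noise. By edgeR or DESeq2 on the reads 0 of the 4 falls were called. So few reads gave an exact binomial p of 0.00216 at best, where edgeR called up to 8.43e-05, so that no cause would have given a call. CLEC2L, GPX7 and SPATA31A3 each had an exact binomial p of 0.0639, against limma adjusted p of 0.0265 to 0.0314. The spread that limma used for these genes was thus below counting error, while its source stays open. No biological explanation of these falls was tested.

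Markers of fibroblasts, endothelium and blood were higher in starved DKO. Fibroblasts mixed into the DKO libraries would bring all their abundant transcripts, but while CDH2 was higher by 643 normalised reads, COL1A2 was higher by 116, COL3A1 by 14.8 and DCN by 4.48, and LUM differed by −0.722. COL1A1, already at 1006 in starved WT, was higher by 648; the median of the 5 was 14.8, which argues against fibroblasts as the whole source, while a part in COL1A1 stays open and endothelial and blood cells were not tested. This median was taken after 2 other forms had been seen, a sum of the means without COL1A1 (144), which also argued against fibroblasts, and that sum with the rise of COL1A1 added, which left them undecided. Derepression of genes silent in WT may explain the rise and cannot be told apart from a general one: 8 of 9 markers under 10 normalised reads in starved WT rose (median 3.64), as did 7 of 7 expressed ones (median 0.72), but the filter keeps a silent marker mostly when it is higher in DKO, and DCN, LUM, POSTN and CDH5, also under 10, were left out by it.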

How the results depend on the processing

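The settings with edgeR, DESeq2, voom, library-total and TMM scaling were chosen after seeing the data, apart from DESeq2 for the overlap. So were the filter on compared groups and the GC and length trend. The others were planned, and edgeR with TMM was the test planned for raw counts. The form of the GC setting that keeps each library's level replaced a first form after the result of that first form was seen, and both are given. The number of genes responding to EGF in WT (17) was 9 with no filter, 125 with a pseudocount of 0.1 (56 higher and 69 lower), 0 with the compared groups only, 30 with the filter on compared groups, 29 with edgeR TMM, 27 with RLE, 28 with DESeq2 and 57 with either GC form. In DKO (91) it was 61 with a pseudocount of 0.1 (59 higher and 2 lower) and 143 under quantile scaling. It was 197 with edgeR TMM (133 higher and 64 lower), 192 with RLE, 153 with DESeq2 and 175 with voom. With the GC trend removed it was 280, and 309 with the level removed too. The difference (17) was 10 with no filter, 41 with a pseudocount of 0.1 (31 higher and 10 lower), and 34 and 36 with the GC forms. The overlap (13 shared rises, 0 shared falls) was 8 with no filter, 0 with the compared groups only, 24 with the filter on compared groups, 26 and 24 with edgeR TMM and RLE (1 shared fall in each), 25 with DESeq2, 44 with either GC form and 6 at an adjusted p under 0.01. With no filter more genes share the adjustment, and with the compared groups only fewer libraries give the spread; elsewhere the cause was not tested. Total counts of DKO against WT stayed within 1.5 times in every setting run, but not their split: with the GC trend and mean level removed it was 3893 higher and 10328 lower starved, and 3844 and 10406 with EGF.

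Leaving out each library in turn, where the lone sample is assumed to vary like the other groups, gave 5 to 67 genes in WT, 27 to 2160 in DKO, 3 to 24 for the difference and 4 to 62 for the overlap. The 2160 and the 62 (28 shared rises and 34 shared falls) came without EGF-treated DKO replicate 2 and the 3 without starved DKO replicate 2. DKO against WT gave 9311 to 12329 starved and 9748 to 11701 with EGF. In WT the 5 came without either starved DKO library and the 67 without either DKO library with EGF. Passing lists numbered 3 to 7 in WT (3 without starved WT replicate 2, 4 without EGF-treated WT replicate 1), 3 to 10 in DKO (3 without EGF-treated DKO replicate 2), 4 to 9 for the difference (9 without starved DKO replicate 2), 10 starved and 9 with EGF. With an estimated correlation 0 of 7, 3 of 9, 1 of 5, 1 of 10 and 1 of 9 lists passed.

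With the replicate block the counts were 25, 119, 23, 11649 and 11728, with 17, 91, 17, 11233 and 11297 of the unblocked calls among them, and 9 lists passed for the difference against 5. Deviations of libraries with the same number had correlations of −0.0049 to 0.0857, which gave little sign that the numbers pair the samples. The block raised the count in each contrast, so that some pairing is not excluded.

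Turning of direction was checked only for the lists, the genes that the rule names and the genes whose EGF response differed. Among those called in the main fit, turning was seen in few cases. Over all calls of DKO against WT, quantile scaling kept call and direction for 7746 of 11256 starved and 8007 of 11315 with EGF. Library-total scaling kept 9406 and 9681. Medians of some lists not called in the main fit also changed sign under quantile scaling. That of NF-kB targets went from 0.10 to −0.20 in starved cells, and that of glucocorticoid receptor targets from 0.14 to −0.16 with EGF. Under quantile scaling the test of the cell cycle list pointed up without passing, while its medians stayed just below 0, at −0.0523 and −0.00544 without and with EGF. With the GC trend and mean level removed, MAPK3 (−0.36), SHC1 (−0.45), TNFAIP2 (−0.0156) and EGFR (−0.11) turned in starved cells, and SHC1 (−0.46), TPM4 (−0.16) and EGFR (−0.30) with EGF. That setting takes out each library's mean and moved the median of all genes to −0.52, and none of these genes turned when the trend alone was removed. Apart from the main counts, 272 values lost the call, 102 gained it, 9 turned and 82, which are counts, moved. Turning was recorded only for the lists and genes checked, and only where they were called in the main fit. The other 12420 values were labelled unchanged, and those not called in the main fit may have changed sign. Of the main counts, 182 values stayed and 58 moved. Depth limits genes with a few reads, as the counting intervals show.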

Other observations

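The tests of ligands and of gene families in this part were chosen after the data were seen, except that the expectation for zinc finger genes was written before its result. Between starved DKO and WT, 14 gene families defined by symbol were compared with the other tested genes by Fisher's exact test, adjusted over the families. Of the clustered protocadherin genes PCDHB, which encode neuronal adhesion proteins, 17 of 17 rose (median 3.48, or 0.95 under quantile scaling, adjusted p = 3.24e-07). Collagen genes rose in 33 of 40 cases (4.41e-08), histone genes in 21 of 25 (6.98e-06), serpins in 13 of 16 (9.99e-04), keratins in 18 of 27 (0.00517), HOX genes in 21 of 35 (0.0143) and tudor domain genes, several of which act in the germline, in 7 of 9 (0.0277). Quantile scaling lowered the medians from 1.26 to 0.08 for histone, 1.18 to 0.14 for keratin, 2.49 to 1.44 for collagen, 1.46 to 0.66 for serpin, 1.31 to 0.44 for HOX and 2.54 to 1.11 for tudor genes. The filter keeps a gene silent in WT mostly when it is higher in DKO, so that rises in families with silent members are partly set by it. Neighbouring genes of a cluster are not independent, as the exact test takes them to be. The poly(A) protocol makes histone levels uncertain. Ribosomal protein genes fell in 72 of 76 cases (2.42e-32), with a median of −0.70, which was −0.38 under quantile, −0.51 under library-total and −0.70 under TMM scaling. Proteasome genes fell in 26 of 38 cases (3.74e-06), with a median of −0.22 that was 0.01 under quantile scaling, and MCM genes in 6 of 9 (0.0367). Claudin (9 of 15 higher), TRIM (27 of 60) and olfactory receptor genes (8 of 18) did not pass, and their medians turned under quantile scaling.

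A hypothesis is that KRAB and other zinc finger genes, many of them in methylated clusters, may rise more often than other genes when DNMT1 and DNMT3B are lost. Of 501 tested ZNF symbols 47.7% were higher in starved DKO, against 36.7% of the other genes (adjusted p = 4.43e-06). The shares were 34.5% against 26.9% under quantile, 55.3% against 46.6% under library-total and 47.5% against 36.5% under TMM scaling. The median ZNF change was −0.10 under quantile scaling, so that the higher share, not a rise of the family as a whole, is what the scalings have in common. The other genes were not matched to the ZNF genes for expression level. With the stricter filter (a value of 50) rises among all genes went from 6290 to 4530 and falls from 4966 to 4820. Rises were thus more frequent among low genes, and an effect of level on the ZNF share was not tested. The single DKO line limits this comparison as it does every genotype comparison.

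A second hypothesis was that EREG, AREG, TGFA and BTC, ligands of the EGF receptor, may be lower in starved DKO because ERK output is lower. It takes their genes to respond to ERK, which was not tested here. With EGF in WT none of them was called. Their means went from 2260 to 2819 (EREG), 1605 to 1846 (AREG), 491 to 539 (TGFA) and 34.0 to 39.1 (BTC). Of 10 genes taken as ERK output, PHLDA1, SPRY4, ETV4 and ETV5 were lower in starved DKO, SPRY2, DUSP6, CCND1, EPHA2 and EPHA4 higher, and DUSP4 did not pass, 4 against 5 with a median change of 0.26. Of all 16972 tested genes 4966 were lower and 6290 higher. The immediate early list, fixed before the data were examined, had 13 members lower and 4 higher (camera adjusted p = 0.00226, or 0.282 with an estimated correlation). Members that go both ways leave the question of ERK output open. The bound for the 10 genes was changed with the result known. Under the earlier bound, fewer than 5 lower, the 4 lower genes argued against lower ERK output. Phosphorylated ERK was not analysed here.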
